A study of Mus musculus with 97 samples.

How the data were processed

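RNA of whole hearts (59 libraries) and flushed jejuna (38 libraries) of C57BL/6 mice was sequenced, with 5 to 8 animals per group in 14 groups. Per the labels' protocols, heart libraries were made with a stranded poly-A kit and jejunum libraries with ribosomal RNA depletion, because jejunum RNA had low RIN scores. Animal numbers are specific to treatment and experiment per the labels, so each library was taken as a separate animal. The deposited values are estimated counts per gene, made by the authors with Salmon 1.9.0 and R 4.2.2 against the GRCm38 build, per the submitters' processing notes. How transcript estimates were summed to genes is not given in the sources used here. The table holds 51368 genes, and all its columns were used. Of its values, 24.7% were not whole numbers, as estimated counts need not be.

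Here the estimated counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Genes were kept with filterByExpr at a minimum count of 10, libraries were scaled by TMM, and robust quasi-likelihood F tests were run in edgeR. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p of 0.05. Counts of genes at an unadjusted p below 0.05 are given too. Without any effect a share of about 0.05 of the tested genes is expected there, so a lower share shows no excess. The share ran from 2.65% for tryptophan in the jejunum to 18.7% for naproxen against celecoxib. One model was fitted per experiment with all of its groups. Dissection batch was a block in experiments 3 and 4, where the labels give it. The pooled naproxen comparison used 35 libraries with experiment 1 females, experiment 1 males and experiment 2 as blocks. The effect in experiment 2 was set against that in the females of experiment 1 in a joint model with experiment as a block. Levels are CPM (counts per 1e6 counts of the TMM-scaled library size), given as mean and SD over animals, and standard errors of log2 fold changes come from the fitted models.

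Of the 17 comparisons, 10 were made in the heart and 7 in the jejunum. All groups, comparisons, gene lists, the model and the first set of alternatives were fixed before the data were examined. Of 54 gene lists, 44 could be tested in the heart and 47 in the jejunum with at least 5 tested members. They were tested with camera of limma on log2 CPM (prior count 2) at a preset correlation between genes of 0.01, and p-values were adjusted over the lists of a comparison. Each list was tested again with a correlation estimated from the data and with fry. Of 261 list calls at the preset correlation, 1 held with an estimated correlation and 10 with fry; the preset value treats members of a list as nearly independent. Where members are said to be called when adjusted over the list alone, only the members' own p-values entered the adjustment.

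Genes named in the text follow a rule written before the data were examined. For the pooled naproxen comparison, naproxen plus tryptophan against control and tryptophan alone in the heart, and the 4 comparisons with control in the jejunum, it takes called genes with a mean of at least 1 CPM in a group and the same sign in every batch or stratum. Predicted genes and immunoglobulin or T-cell receptor segments are left out, and the 8 largest rises and 8 largest falls are kept. From each called list it takes up to 4 called members with the smallest p, and from every other list the called member with the smallest p. Ptgs1 and Ptgs2 are always taken, and where fewer than 5 genes pass, the 5 genes with the smallest p. The other comparisons take 4 rises and 4 falls, or the 5 genes with the smallest p. Members named as examples of a list fall outside this rule: they were chosen after their values were seen, as those with the lowest p of their list. Not every gene the rule takes is printed, and the results of some are not reported here. Coordinates of 100 named genes were matched by Ensembl ID to the GENCODE annotation of the same build. Counts of multicopy families such as ribosomal proteins, immunoglobulin segments, histones and defensins depend on how reads were shared between near-identical copies.

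Depth by library was 10.11 to 76.36 (in units of 1e6 estimated counts), with medians of 29.77 in experiment 1, 53.74 in experiment 2, 50.66 in experiment 3 and 19.08 in the jejunum. The most abundant gene took 4.058% to 21.97% of counts in the jejunum and 7.716% to 14.4% in the hearts. The tests were first run on simulated counts drawn around the measured means, with a set of 200 genes changed by known folds. In the pooled naproxen simulation (15579 genes) edgeR recovered 64 of 67 genes changed 1.5-fold, and 3.47% of its calls were false. In the simulation of the females of experiment 1 it recovered 37 of 67 genes at 1.5-fold and 59 of 67 at 2-fold, with 4.14% of calls false, while 17.6% of DESeq2 calls were false there. In the jejunum naproxen simulation it recovered 36 of 67 genes at 1.5-fold and 56 of 67 at 2-fold. The simulated noise was independent between genes, so in tissue whose composition varies, fewer changed genes and more false calls than these shares can arise. Replicates of a group were checked for copies: the lowest chi-square per degree of freedom of any pair was 17.1 and 0 pairs were identical. Of 165 immunoglobulin segments tested in the jejunum, edgeR called 0 in any comparison (16 to 32 at an unadjusted p below 0.05), while among the segments with the lowest p some were called under alternatives, as Ighv1-76 for naproxen plus tryptophan against naproxen in 3 of 13.

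The alternatives tried were DESeq2, RLE scaling, no filter beyond 1 read, voom with quality weights, the replicate number of the labels as a block, only the compared groups in the model, no dissection batch, a smooth muscle score as a covariate in the jejunum, and omission of each library in turn. For the pooled comparison, females only and experiment 1 only were fitted. Added after the data were seen were 1, 2 or 3 surrogate variables, DESeq2 without the filter, components of the clock list or the erythroid score as covariates, and omission of libraries that stood apart. Correlations of fold changes between comparisons that share controls were set beside simulations without effects and beside fits with the controls split. The closing section gives what each alternative changed. Expression levels were not tested between tissues, because library types differed. Controls of different experiments were not tested against each other, because each experiment was a distinct cohort. Between experiment 1 and the others, injections differed as well.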

Results

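Naproxen and celecoxib are non-steroidal anti-inflammatory drugs that inhibit the cyclooxygenases encoded by Ptgs1 and Ptgs2, and tryptophan is the amino acid from which serotonin, kynurenines and indoles are made. The series asks how these treatments, given alone or together, change transcript levels in the whole heart and in the jejunum of C57BL/6 mice. It holds 97 libraries in 14 groups, 87 from females and 10 from males. Per the labels, mice ate NSAID-supplemented or normal chow for 3 weeks and were 11 weeks old at the end. Celecoxib was given at 550 ppm and naproxen at 1323 ppm to females and 1610 ppm to males. Tryptophan was injected daily at 50 mg/kg during the last week, and the other mice of those experiments received PBS, while the mice of experiment 1 received no injection. The labels describe each experiment as a distinct cohort.

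Experiment 1 compared naproxen with control in hearts of females (5 and 5) and males (5 and 5). Experiment 2 compared control (8), naproxen (7) and naproxen plus tryptophan (8) in female hearts, and experiment 3 compared tryptophan (8) with control (8) in female hearts. Experiment 4 took the jejunum of females on control (8), celecoxib (8), naproxen (7), tryptophan (8) and naproxen plus tryptophan (7). Dissection batches were labelled for experiments 3 and 4 only and were fitted there as blocks. Heart libraries were poly-A selected and jejunum libraries were depleted of ribosomal RNA, so the tissues were analysed separately.

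Estimated counts per library, in units of 1e6, summed to 26.3 to 32.47 in experiment 1, 28.42 to 67.14 in experiment 2, 41.4 to 76.36 in experiment 3 and 10.11 to 28.54 in the jejunum. Mitochondrial transcripts made up 18.48% to 39.23% of counts in the hearts and 3.112% to 12.5% in the jejunum. Xist was read at 211 to 2050 CPM (counts per 1e6 counts) in female libraries and at no more than 0.863 CPM in male libraries, and Ddx3y at 85.1 to 119 CPM in males and 0 CPM in females. Among the 2000 most variable genes, the first component of the jejunum carried 25% of variance, of which dissection batch accounted for 38%. In experiment 3 the first component carried 26.9%, of which dissection batch accounted for 55.9%. Treatment group accounted for 3.23% of the first and 21.1% of the second component in experiment 2, and for 35.4% of the second in the jejunum. The groups of experiment 1, which combine sex and treatment, accounted for 15% of its first and 83.8% of its second component.

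The first question was which heart transcripts differ with naproxen across cohorts and sexes. Ppargc1a encodes a transcriptional coactivator that drives mitochondrial biogenesis, Rnf144b a ubiquitin ligase of the RING-between-RING family, Fnip2 a partner of folliculin in nutrient sensing, and Rhobtb1 an adaptor of cullin 3 ligases. Klra9 encodes a natural killer cell receptor. In the pooled comparison (17 naproxen and 18 control hearts, with females of experiment 1, males of experiment 1 and experiment 2 as blocks), edgeR called 9 genes higher and 5 lower among 15738 tested. DESeq2 called 48 genes in the same comparison and voom 38.

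Rnf144b (ENSMUSG00000038068, chromosome 13, 47122656 to 47247991) rose by log2 0.58 (standard error 0.09, adjusted p = 0.00733). Its mean (± SD) went from 25.6 ± 3.72 to 44.9 ± 14.3 CPM in females of experiment 1, from 28.3 ± 4.59 to 50.0 ± 2.58 CPM in males, and from 34.9 ± 3.96 to 41.5 ± 7.82 CPM in experiment 2. Fnip2 (ENSMUSG00000061175, chromosome 3, 79455974 to 79567796) rose by log2 0.55 (standard error 0.09, adjusted p = 0.00733). The Fnip2 differences by stratum were 0.79 in females and 0.76 in males of experiment 1 and 0.21 in experiment 2. Ppargc1a (ENSMUSG00000029167, chromosome 5, 51454250 to 51567726) rose by log2 0.69 (standard error 0.13, adjusted p = 0.0198). In experiment 2, Ppargc1a stood at 129 ± 24.2 CPM in 8 controls and 199.9 ± 83.6 CPM in 7 naproxen hearts. Rhobtb1 (ENSMUSG00000019944, chromosome 10, 69151434 to 69291791) rose by log2 0.46 (adjusted p = 0.0198), from 101.4 ± 8.76 to 183.4 ± 25.4 CPM in females of experiment 1 and from 225.6 ± 23.3 to 250.3 ± 38.4 CPM in experiment 2. These 4 genes are protein-coding, and each difference was smallest in experiment 2.

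Ppfia1, which encodes liprin alpha 1 of cell adhesion sites, rose by log2 0.39 (adjusted p = 0.0198), and Slc25a33, a mitochondrial pyrimidine nucleotide carrier, by 0.39 (adjusted p = 0.0432). Fam13c fell by log2 0.27 (adjusted p = 0.0198), with differences of -0.26, -0.21 and -0.33 in the 3 strata. Klra9 fell by log2 0.70 (adjusted p = 0.0268), and Sema6a, a transmembrane semaphorin, by 0.35 (adjusted p = 0.0432). Afdn and Gask1b were also lower (adjusted p = 0.0462 and 0.0493). With 1 library left out, Rnf144b, Fnip2, Ppargc1a, Rhobtb1, Ppfia1 and Fam13c were still called in 35 of 35 omissions, Klra9 in 29, Slc25a33 in 14, Sema6a in 11, Gask1b in 8 and Afdn in 6. The pooled count of 14 ranged from 6 to 42 in these omissions. Under the 13 other settings Rnf144b was called in 11, Fnip2, Ppargc1a and Fam13c in 10, and Rhobtb1 and Ppfia1 in 8. With components of the clock list as covariates, 0 of the 14 genes stayed called. The drug targets were not called: Ptgs1 differed by log2 0.19 (adjusted p = 0.524) and Ptgs2 by -0.13 (adjusted p = 1).

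**Figure D1:**
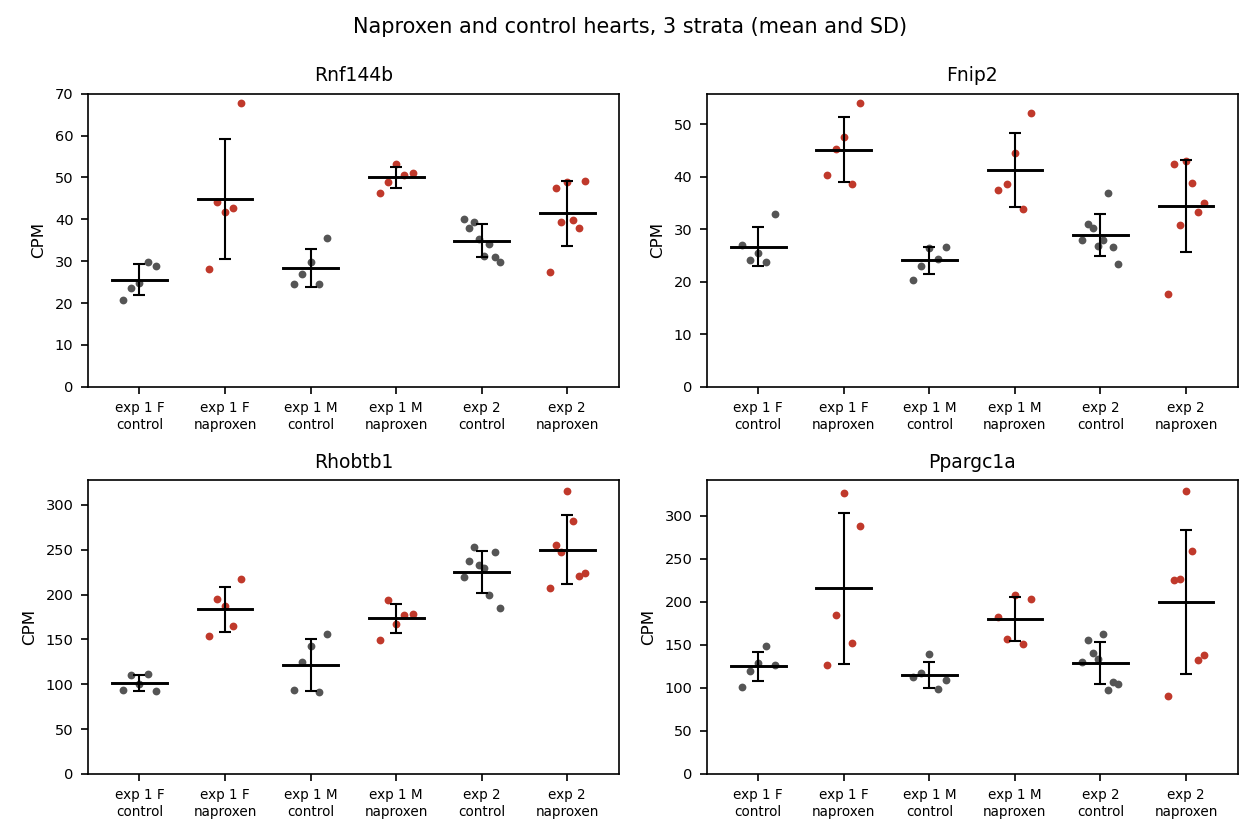
Levels (CPM, vertical axes) of Rnf144b, Fnip2, Rhobtb1 and Ppargc1a in control (grey) and naproxen (red) hearts of experiment 1 females, experiment 1 males and experiment 2 (horizontal axes), 5 to 8 animals per group. Dots are libraries, bars are means and error bars SD; all 4 genes lie higher with naproxen, least so in experiment 2 for Rnf144b, Fnip2 and Rhobtb1.

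Whole-heart RNA includes the blood held in the organ, in which erythroid transcripts come from reticulocytes and S100a8 and its partners from neutrophils. Among the gene lists fixed beforehand, the erythroid markers were higher with naproxen in the pooled comparison (median log2 1.26, 9 of 9 members positive, camera adjusted p = 4.08e-12; adjusted p = 0.459 with an estimated correlation). Of those 9 members, 9 were called when p-values were adjusted over the list alone. Neutrophil markers were higher as well (median 2.01, 8 of 8 positive, adjusted p = 5.18e-07; adjusted p = 0.459 with an estimated correlation), with 6 of 8 called when adjusted over the list alone. By stratum, the neutrophil mean was -0.551 in control and -0.804 in naproxen males (log2 CPM), and the mean of naproxen females (1.06 ± 2.24) included naproxen 3 at 4.88. Glucocorticoid targets showed a median of 0.15 with 19 of 19 positive (adjusted p = 5.18e-07; adjusted p = 0.459 with an estimated correlation), led by Fkbp5 at log2 0.74, which was not called over all genes (adjusted p = 0.153). Extracellular matrix genes were lower (median -0.16, 26 of 31 negative, adjusted p = 7.12e-07; adjusted p = 0.58 with an estimated correlation). In the females of experiment 1 the erythroid mean stood at 4.32 ± 0.482 in 5 controls and 6.37 ± 1.82 in 5 naproxen hearts (log2 CPM). The B-cell list tested lower (adjusted p = 0.0282; adjusted p = 0.734 with an estimated correlation) although its median (0.19) and mean (0.16) were positive.

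**Figure D2:**
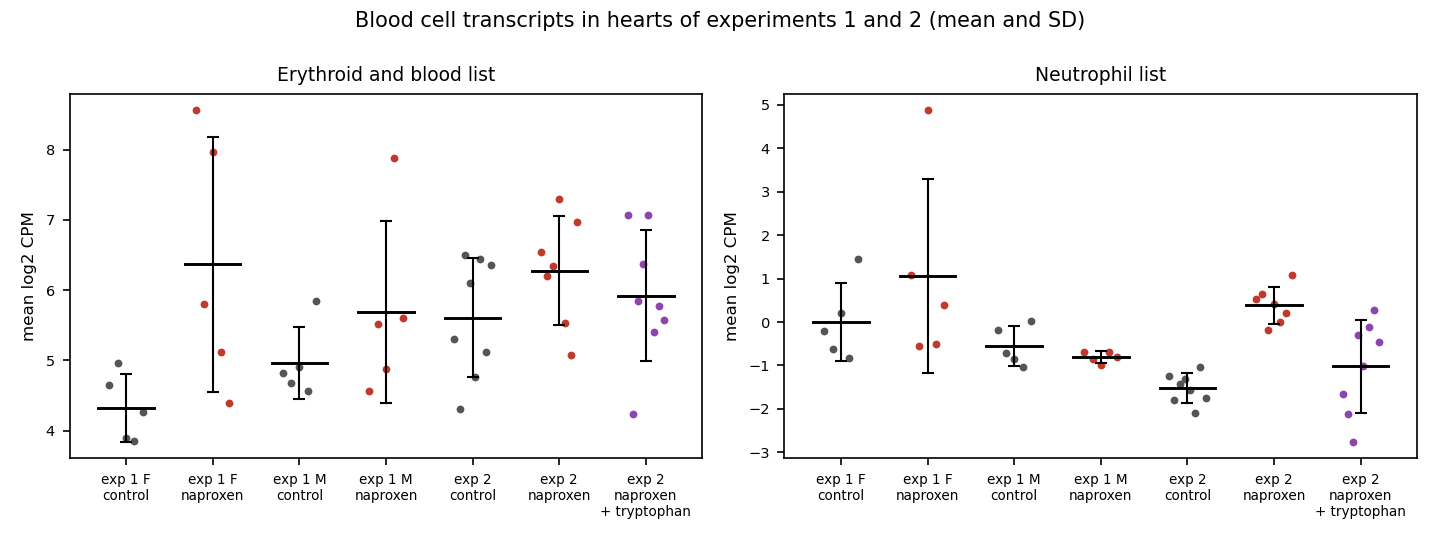
Mean log2 CPM (vertical axes) of the erythroid and the neutrophil marker lists in the 7 heart groups of experiments 1 and 2 (horizontal axes), 5 to 8 animals per group. Dots are libraries, bars are means and error bars SD. Neutrophil markers lie highest in the naproxen group of experiment 2 relative to its controls, and erythroid markers spread widely in naproxen females of experiment 1. The neutrophil mean covers 8 tested members in experiment 2 and 6 in experiment 1, so its levels cannot be compared between experiments.

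Experiment 1 addressed females and males separately. Circadian clock genes such as Per2 and Arntl oscillate in antiphase in the heart, and Sqle encodes an enzyme of cholesterol synthesis. In 5 naproxen and 5 control females, edgeR called 2 genes among 15152: Rhobtb1 rose by log2 0.86 (standard error 0.13, adjusted p = 0.0357) and Fnip2 by 0.76 (standard error 0.12, adjusted p = 0.0357). With 1 library left out they were still called in 2 and 3 of 10 omissions. DESeq2 called 54 genes in the same females and voom 0, and 1082 genes had an unadjusted p below 0.05. Erythroid markers were higher (median 2.49, 9 of 9 positive, adjusted p = 9.86e-10; adjusted p = 0.403 with an estimated correlation). B-cell markers were lower (median -0.71, 11 of 12 negative, adjusted p = 0.000152; adjusted p = 0.571 with an estimated correlation). The clock list tested higher (13 of 18 positive, adjusted p = 0.00181; adjusted p = 0.386 with an estimated correlation), with 7 members called when adjusted over the list alone, 5 of them higher. Fry, which allows both directions, gave that list a mixed adjusted p of 0.0207. Its members with the lowest p were Per2 (log2 0.86) and Arntl (log2 -1.46), neither called over all genes.

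In males the question was the same, and the antigen presentation list, which holds MHC genes of both classes, gave the lowest list p. In 5 naproxen and 5 control males, edgeR called 0 genes, with 1164 at an unadjusted p below 0.05, while DESeq2 called 32 and voom 23. The lowest adjusted p was that of Fnip2 (log2 0.78, adjusted p = 0.0534), followed by Clec11a, which encodes a secreted growth factor of bone marrow (log2 -1.47, adjusted p = 0.301), Rnf144b (log2 0.82, adjusted p = 0.301) and the adrenergic receptor gene Adra1a (log2 0.58, adjusted p = 0.301). Antigen presentation genes were lower (median -0.43, 18 of 18 negative, adjusted p = 4.42e-08; adjusted p = 0.689 with an estimated correlation), among them H2-K1 at log2 -0.62. Transcripts encoded in the mitochondrial genome were higher (median 0.31, 13 of 13 positive, adjusted p = 0.000139; adjusted p = 0.689 with an estimated correlation). Immediate early genes were lower (median -0.33, 19 of 23 negative, adjusted p = 0.000207; adjusted p = 0.689 with an estimated correlation), with Egr2 at log2 -1.39.

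Whether the naproxen effect differed between the sexes was tested as an interaction in the 20 hearts of experiment 1. Naproxen in the chow was 1610 ppm for males and 1323 ppm for females, so sex and dose cannot be told apart in this test. Id1, an inhibitor of basic helix-loop-helix factors, was among the genes with the lowest p. edgeR called 0 genes (765, or 5.05%, at an unadjusted p below 0.05), DESeq2 1 and voom 0, and the lowest adjusted p was 0.759. Rpl12, which belongs to a ribosomal family with many near-identical copies, showed log2 -4.50 (adjusted p = 0.759), and Id1 log2 -0.82. The mitochondrially encoded transcripts differed as a list (median 0.61, 13 of 13 positive, adjusted p = 3.54e-06; adjusted p = 0.594 with an estimated correlation). Control males and females were compared as a reference for known sex differences. There edgeR called 14 genes higher and 9 lower in males, DESeq2 59 in all and voom 25. The X-inactivation transcript Xist fell by log2 10.92 (adjusted p = 3.05e-13), and Kdm6a and Eif2s3x, which escape X inactivation, fell by 1.01 and 0.83 (adjusted p = 2.29e-05 and 7.41e-05). The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d averaged 102, 63.8, 25.2 and 20.7 CPM in the 5 control males. The collagen gene Col14a1 fell by log2 0.92 in males (standard error 0.17, adjusted p = 0.0286) and was still called in 2 of 10 omissions of 1 library. PPAR alpha targets of fatty acid oxidation were higher in males (median 0.17, 34 of 38 positive, adjusted p = 1e-04; adjusted p = 0.907 with an estimated correlation).

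Experiment 2 asked whether naproxen acts in the hearts of females that also received daily PBS injections. S100a8 encodes a calcium-binding protein abundant in neutrophils, Slfn4 a myeloid Schlafen protein, and Gli1 the transcription factor that reads out hedgehog signalling. In 7 naproxen and 8 control hearts edgeR called 0 genes among 16085, while DESeq2 called 6 and voom 7. At an unadjusted p below 0.05 there were 584 genes (3.63%), a lower share than expected without any effect. The genes with the lowest p were Slfn4 (log2 2.27), Gli1 (log2 -0.67) and S100a8 (log2 2.74), each at an adjusted p of 0.262. Neutrophil markers were higher as a list (median 2.21, 8 of 8 positive, camera adjusted p = 1.04e-16; adjusted p = 0.0091 with an estimated correlation; fry adjusted p = 0.00842). This was the only list call in any comparison that held with an estimated correlation. Its adjustment covered the 44 lists of this comparison only, with no allowance for the other comparisons. The neutrophil mean was -1.52 ± 0.344 in controls and 0.386 ± 0.421 in naproxen hearts (log2 CPM). In control and naproxen males of experiment 1 it was -0.551 ± 0.451 and -0.804 ± 0.128. The mean covers 8 tested members in experiment 2 and 6 in experiment 1, so only differences within an experiment can be read. Cell cycle genes were also higher (median 0.53, 31 of 33 positive, adjusted p = 3.1e-17; adjusted p = 0.171 with an estimated correlation), among them Ccna2 at log2 0.88. Inflammatory genes were higher (median 0.42, 14 of 15 positive, adjusted p = 9.02e-06; adjusted p = 0.171 with an estimated correlation).

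The naproxen effect in experiment 2 was then compared with that in the females of experiment 1. Per2 encodes a repressor in the circadian feedback loop, and Arntl its antiphase activator. Per2 (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324) was the 1 gene called by edgeR among 16174 (log2 -0.98, standard error 0.13, adjusted p = 0.000669); DESeq2 called 9 and voom 5. Per2 stood at 23.7 ± 2.98 and 42.9 ± 2.86 CPM in control and naproxen females of experiment 1 (5 and 5), and at 48.3 ± 5.18 and 44.9 ± 5 CPM in experiment 2 (8 and 7). The clock list differed between the experiments (median -0.27, 15 of 18 negative, adjusted p = 8.21e-05; adjusted p = 0.361 with an estimated correlation). Erythroid markers also differed (median -2.02, 9 of 9 negative, adjusted p = 8.21e-05; adjusted p = 0.99 with an estimated correlation). Collection times were not given in the labels.

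The combination of naproxen and tryptophan was compared with control in experiment 2. Eno3 encodes the muscle enolase of glycolysis, Slc2a12 a glucose transporter, Apold1 an endothelial immediate early protein, and Tnnc1 the slow troponin C of the sarcomere. Csf1 encodes the growth factor of macrophages, and Ahr the aryl hydrocarbon receptor, to which tryptophan metabolites bind. In 8 and 8 hearts edgeR called 30 genes higher and 11 lower, with 2761 at an unadjusted p below 0.05, while DESeq2 called 477 and voom 2830. The edgeR count of 41 ranged from 7 to 83 with 1 library left out, and was lower in 14 of 16 omissions. Eno3 (ENSMUSG00000060600, chromosome 11, 70657202 to 70662513) rose by log2 0.47 (standard error 0.08, adjusted p = 0.00997), from 971.8 ± 79.8 CPM in controls to 1344 ± 123 CPM, with 1038 ± 119 CPM on naproxen alone. Slc2a12 (ENSMUSG00000037490, chromosome 10, 22645011 to 22704285) rose by log2 0.46 (standard error 0.08, adjusted p = 0.0102). Apold1 (ENSMUSG00000090698, chromosome 6, 134981718 to 134986836) rose by log2 1.00 (standard error 0.17, adjusted p = 0.0148), from 6.15 ± 1.4 to 12.3 ± 2.48 CPM.

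Sik1, a salt-inducible kinase, rose by log2 1.29 (standard error 0.27, adjusted p = 0.0454) with the combination, and the elongation factor gene Ell2 by 0.75 (adjusted p = 0.0379). Tnnc1 rose by log2 0.41, Abra by 0.53 and Tesc by 0.51 (adjusted p = 0.0454 each). Csf1 (ENSMUSG00000014599, chromosome 3, 107741048 to 107760469) fell by log2 0.45 (adjusted p = 0.0208), from 44.1 ± 4.46 CPM in controls to 32.4 ± 1.88 CPM, with 44.1 ± 7.12 CPM on naproxen alone. Ahr (ENSMUSG00000019256, chromosome 12, 35497974 to 35535038) fell by log2 0.62 (standard error 0.13, adjusted p = 0.0454), from 7.93 ± 1.72 to 5.16 ± 0.647 CPM, with 7.78 ± 1.57 CPM on naproxen alone. Adam22 fell by log2 0.40 (adjusted p = 0.0352), and Corin, which encodes the protease that activates natriuretic peptides, by 0.28 (adjusted p = 0.0454). With 1 library left out, Eno3, Slc2a12 and Apold1 were still called in 16 of 16 omissions, Csf1 in 10, Adam22 in 9, Ahr and Corin in 4, and Ell2, Sik1, Tnnc1, Abra and Tesc in 3. Under the 12 other settings Eno3 was called in 11 (log2 0.23 to 0.48, adjusted p = 6.85e-08 to 0.854), Slc2a12 in 9 and Apold1 in 8, and none of the 3 was called with the clock components as covariates. Ptgs1 (log2 -0.25, adjusted p = 0.279) and Ptgs2 (log2 -0.33, adjusted p = 0.574) were not called.

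**Figure D3:**
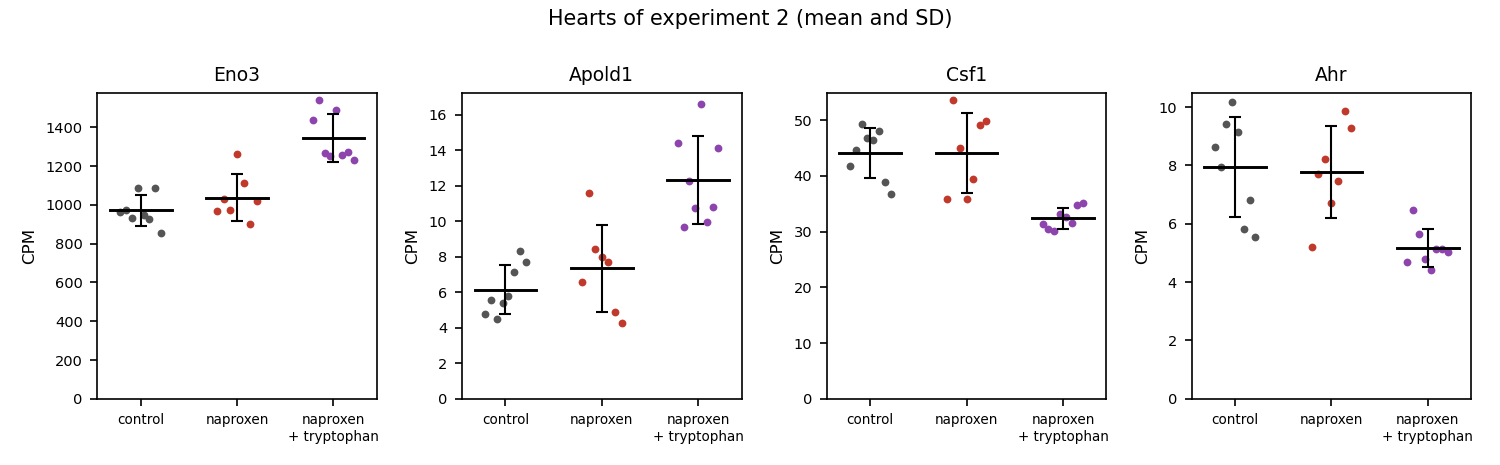
Levels (CPM, vertical axes) of Eno3, Apold1, Csf1 and Ahr in control, naproxen and naproxen plus tryptophan hearts of experiment 2 (horizontal axes), 7 or 8 animals per group. Dots are libraries, bars are means and error bars SD; Eno3 and Apold1 lie higher and Csf1 and Ahr lower in the naproxen plus tryptophan group than in controls.

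Nuclear genes of the respiratory chain were higher with the combination than in controls (median 0.33, 38 of 39 positive, adjusted p = 8e-17; adjusted p = 0.461 with an estimated correlation; fry adjusted p = 0.0292). Of these 39 genes, 30 were called higher when p-values were adjusted over the list alone, led by Cyc1 (log2 0.33), which was not called over all genes (adjusted p = 0.0549). Ribosomal protein genes were higher (median 0.37, 40 of 40 positive, adjusted p = 1.38e-11; adjusted p = 0.894 with an estimated correlation). Heat shock genes were higher (median 0.29, 13 of 15 positive, adjusted p = 3.1e-06; adjusted p = 0.432 with an estimated correlation; fry adjusted p = 0.0139), among them Hspa1b at log2 1.46. Immediate early genes were higher (median 0.23, 16 of 23 positive, adjusted p = 0.000893; adjusted p = 0.894 with an estimated correlation). The tryptophan metabolism list was not called (10 of 14 negative, adjusted p = 0.132), nor was the list of Ahr targets (adjusted p = 0.859).

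To separate the part that tryptophan adds, naproxen plus tryptophan was compared with naproxen alone. Rin1 encodes a Ras effector, and Fbxl22 an F-box protein of the sarcomere. edgeR called 6 genes higher and 9 lower in 8 and 7 hearts, DESeq2 80 and voom 563. Rin1 fell by log2 0.65 (standard error 0.11, adjusted p = 0.0295), and Csf1 by 0.45 and Lratd1 by 0.98 (adjusted p = 0.0367 each). Cryba4 rose by log2 0.64, Fbxl22 by 0.52 and Plekhf1 by 0.44 (adjusted p = 0.0367 each), and Tll2 by 1.15 (adjusted p = 0.0409). With 1 library left out, Rin1 was still called in 7 of 15 omissions, Csf1 and Fbxl22 in 5, Tll2 in 4, Cryba4 and Plekhf1 in 3 and Lratd1 in 2. Cryba4 was higher against controls too (log2 0.55, adjusted p = 0.0454), a call that held in 2 of 16 omissions. Neutrophil markers were lower than on naproxen alone (median -1.16, 7 of 8 negative, adjusted p = 4.5e-07; adjusted p = 0.162 with an estimated correlation; fry adjusted p = 0.0333). Heat shock genes were higher (median 0.26, 13 of 15 positive, adjusted p = 1.03e-07; adjusted p = 0.162 with an estimated correlation; fry adjusted p = 0.0239). Respiratory chain genes were higher (median 0.22, 37 of 39 positive, adjusted p = 5.19e-11; adjusted p = 0.418 with an estimated correlation).

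Experiment 3 asked what tryptophan does in the heart without naproxen. Fkbp5 is a co-chaperone induced by glucocorticoids, and Cx3cr1 a fractalkine receptor of macrophages. With dissection batch as a block, edgeR called 0 genes among 15805 in 8 and 8 hearts (459, or 2.9%, at an unadjusted p below 0.05), DESeq2 2 and voom 0. The genes with the lowest p were Csf2rb (log2 0.57), Cx3cr1 (log2 0.70) and Fkbp5 (log2 -0.50), each at an adjusted p of 1. Glucocorticoid targets were lower as a list (median -0.15, 17 of 19 negative, adjusted p = 2.65e-08; adjusted p = 0.058 with an estimated correlation), with Fkbp5 at 21.8 ± 7.95 CPM in controls and 15.0 ± 3.31 CPM with tryptophan. Macrophage markers were higher (median 0.13, 12 of 14 positive, adjusted p = 1.61e-05; adjusted p = 0.447 with an estimated correlation). The tryptophan metabolism list (adjusted p = 0.355) and the Ahr targets (adjusted p = 0.574) were not called.

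In the jejunum the first question was the effect of naproxen. Ntan1 encodes an amidase that acts on N-terminal asparagine and marks proteins for degradation, and Rbbp9 a serine hydrolase. Paneth cells secrete antimicrobial peptides such as the alpha-defensins, and Adipoq and Lep are made by white adipocytes, which lie in the mesentery attached to the gut. In 7 naproxen and 8 control jejuna edgeR called 0 genes higher and 2 lower among 17185 (2754 at an unadjusted p below 0.05), DESeq2 94 and voom 0. With 1 library left out the count ranged from 0 to 8, and Ntan1 and Rbbp9 were each still called in 4 of 15 omissions. Ntan1 (ENSMUSG00000022681, chromosome 16, 13818845 to 13835451) fell by log2 0.48 (standard error 0.09, adjusted p = 0.0496), from 28.1 ± 3.33 to 20.1 ± 2.36 CPM, with differences of -0.19, -0.42, -0.70 and -0.71 in the 4 dissection batches. Rbbp9 (ENSMUSG00000027428, chromosome 2, 144542265 to 144550869) fell by log2 0.40 (standard error 0.07, adjusted p = 0.0496), from 13.1 ± 1.51 to 9.89 ± 1.23 CPM. In the other groups Ntan1 averaged 23.1 CPM with celecoxib, 24.0 CPM with tryptophan and 21.5 CPM with the combination. Plaat3 (log2 -0.81), H2ac18 (log2 -1.18) and Sprr2a2 (log2 1.48) followed, each at an adjusted p of 0.0898. Ptgs1 (log2 0.41, adjusted p = 0.411) and Ptgs2 (log2 0.33, adjusted p = 0.677) were not called.

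Respiratory chain genes were lower in the naproxen jejunum (median -0.35, 39 of 39 negative, adjusted p = 1.6e-16; adjusted p = 0.521 with an estimated correlation), with 18 called when adjusted over the list alone. Ribosomal protein genes were lower (median -0.33, 40 of 40 negative, adjusted p = 1.25e-14; adjusted p = 0.521 with an estimated correlation). Paneth cell genes were lower (median -0.83, 15 of 15 negative, adjusted p = 7.06e-06; adjusted p = 0.521 with an estimated correlation), among them Itln1 at log2 -0.92 and Lyz1 at -0.84. Naproxen 7 had the lowest Paneth mean of its group (5.63 log2 CPM), and the mitochondrial share of counts was 12.5% and 12.1% in naproxen 6 and 7 against 4.22% to 8.52% in controls. In naproxen 6 the mitochondrial ribosomal RNA mt-Rnr2 alone took 8.08% of counts. The signal recognition particle RNA Rn7s1 took 22.0% and 15.3% of counts in naproxen 4 and 5 and at most 11.9% in controls. Goblet cell genes were lower (median -0.38, 13 of 13 negative, adjusted p = 7.13e-05; adjusted p = 0.521 with an estimated correlation). Absorptive enterocyte markers were lower (median -0.32, 21 of 22 negative, adjusted p = 7.09e-05; adjusted p = 0.521 with an estimated correlation), with a mean of 9.90 ± 0.383 in controls and 9.39 ± 0.673 with naproxen (log2 CPM), lowest in naproxen 1 at 8.08. White adipocyte markers were lower (median -1.48, 10 of 12 negative, adjusted p = 0.000229; adjusted p = 0.521 with an estimated correlation), with Adipoq at log2 -3.45 (adjusted p over all genes = 0.174). The adipocyte mean was 3.06 ± 0.959 in controls and 1.67 ± 1.09 in naproxen jejuna (log2 CPM). Smooth muscle markers were not called (median 0.30, adjusted p = 0.271). The tryptophan metabolism list was lower (12 of 17 negative, adjusted p = 0.0153; adjusted p = 0.521 with an estimated correlation), with Ido1 at log2 -1.04.

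**Figure D4:**
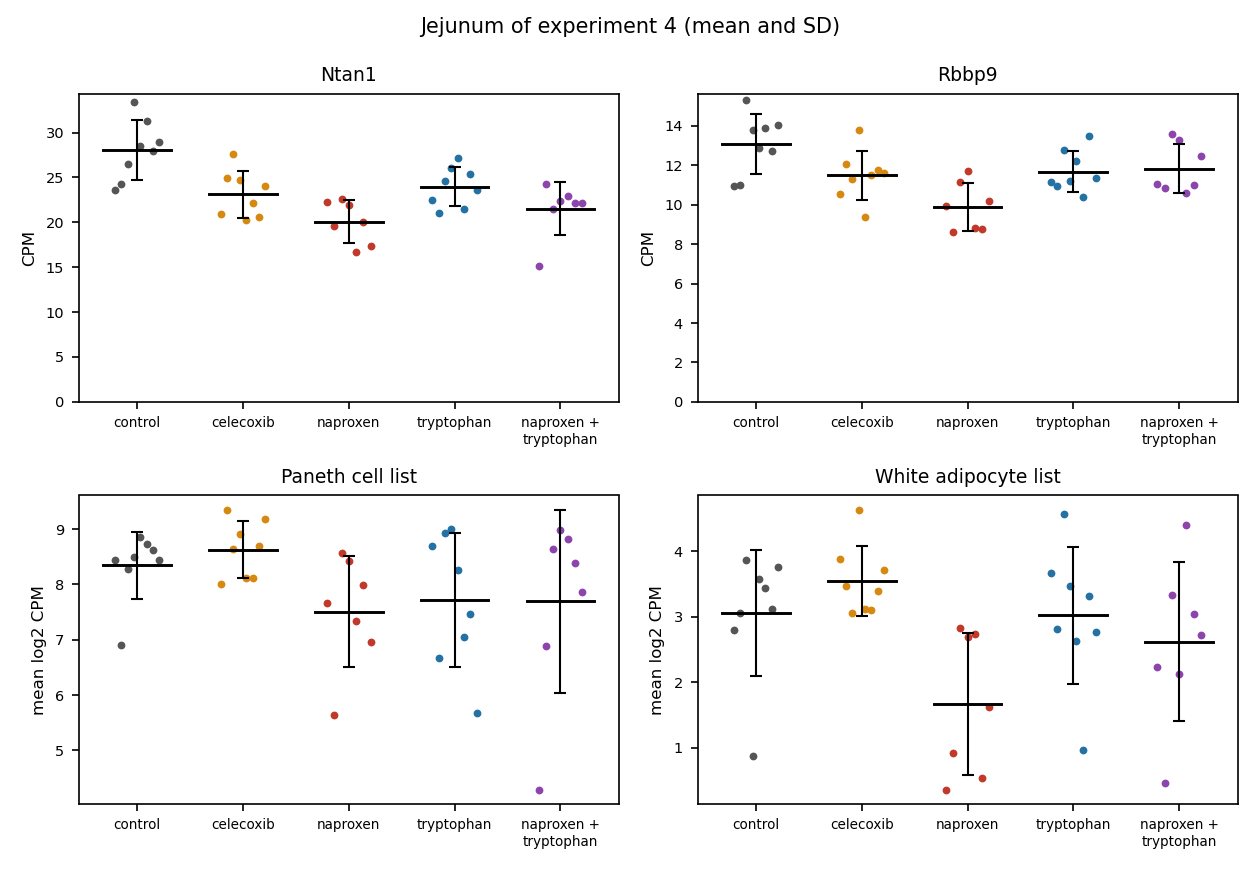
Ntan1 and Rbbp9 (CPM) and the Paneth cell and white adipocyte lists (mean log2 CPM) on the vertical axes in the 5 jejunum groups (horizontal axes), 7 or 8 animals per group. Dots are libraries, bars are means and error bars SD; Ntan1 and Rbbp9 lie lowest in the naproxen group, and the 2 lists spread widely within groups.

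Celecoxib, which inhibits cyclooxygenase 2 selectively, was compared with control in 8 and 8 jejuna. Cyp1a1 encodes a cytochrome P450 induced through the aryl hydrocarbon receptor. edgeR called 0 genes (751, or 4.37%, at an unadjusted p below 0.05), DESeq2 0 and voom 0, and the lowest adjusted p was 0.957. Among the genes with the lowest p were Card14 (log2 0.61) and Cyp1a1 (log2 -2.29, standard error 0.63), the latter at 13.6 ± 7.76 CPM in controls and 3.19 ± 2.06 CPM with celecoxib. Extracellular matrix genes were lower (median -0.39, 31 of 31 negative, adjusted p = 1e-07; adjusted p = 0.582 with an estimated correlation), among them Col1a1 at log2 -0.74. T and NK cell markers were lower (median -0.42, 17 of 18 negative, adjusted p = 1.35e-05; adjusted p = 0.448 with an estimated correlation). The neutrophil mean was 1.31 ± 0.667 in controls and 0.811 ± 0.497 with celecoxib (log2 CPM), and the thymus mean 1.88 ± 0.411 and 1.58 ± 0.277. The Paneth mean went the other way (8.34 ± 0.612 and 8.63 ± 0.511). Control 1 had the highest neutrophil (2.31), plasma cell (5.53) and smooth muscle (7.42) means of its group and the lowest absorptive enterocyte mean (9.08). Ahr targets were lower (median -0.25, 10 of 11 negative, adjusted p = 0.0142; adjusted p = 0.34 with an estimated correlation). Cholesterol synthesis genes were higher (median 0.17, 25 of 25 positive, adjusted p = 0.000519; adjusted p = 0.582 with an estimated correlation). Ptgs1 (log2 -0.21) and Ptgs2 (log2 -0.09) were not called.

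Naproxen and celecoxib were then compared directly, which sets a non-selective against a selective inhibitor. Kars encodes lysyl-tRNA synthetase, and Hpd an enzyme of tyrosine breakdown. edgeR called 0 genes with 3211 at an unadjusted p below 0.05, while DESeq2 called 291 and voom 0. The edgeR count ranged from 0 to 498 with 1 library left out, the highest without naproxen 6, in which mitochondrial transcripts made up 12.5% of counts (8.08% from mt-Rnr2). The genes with the lowest p were Kars (log2 -0.52), Mpp3 (log2 0.96), Shisa2 (log2 -0.64), Hpd (log2 -1.21) and Spindoc (log2 0.72), each at an adjusted p of 0.0643. Cell cycle genes were lower with naproxen (median -0.38, 33 of 33 negative, adjusted p = 1.73e-14; adjusted p = 0.519 with an estimated correlation), 13 of them called when adjusted over the list alone. Paneth cell genes were lower (median -1.14, 15 of 15 negative, adjusted p = 2.78e-08; adjusted p = 0.519 with an estimated correlation), 10 of them called when adjusted over the list alone. White adipocyte markers were lower (median -1.76, 12 of 12 negative, adjusted p = 1.29e-06; adjusted p = 0.519 with an estimated correlation; fry adjusted p = 0.0213). Extracellular matrix genes were higher (median 0.52, 28 of 31 positive, adjusted p = 1.2e-05; adjusted p = 0.519 with an estimated correlation), with Col1a1 at log2 1.58 (adjusted p over all genes = 0.101).

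Tryptophan alone was compared with control in 8 and 8 jejuna, where microbes and epithelium both metabolise it. Gzma and Gzmb encode granzymes of cytotoxic lymphocytes. edgeR called 0 genes (456, or 2.65%, at an unadjusted p below 0.05), DESeq2 0 and voom 0, with a lowest adjusted p of 0.999. Tmem25 (log2 0.61) and Gm2115 (log2 0.66) were among the genes with the lowest p. T and NK cell markers were lower (median -0.52, 17 of 18 negative, adjusted p = 3.74e-12; adjusted p = 0.158 with an estimated correlation), with 5 called when adjusted over the list alone and Gzma at log2 -1.43. Paneth cell genes were lower as well (median -0.41, 15 of 15 negative, adjusted p = 3.27e-05; adjusted p = 0.524 with an estimated correlation), with a mean of 8.34 ± 0.612 in controls and 7.72 ± 1.2 with tryptophan (log2 CPM). The neutrophil mean was 1.31 ± 0.667 and 0.929 ± 0.579, and the thymus mean 1.88 ± 0.411 and 1.51 ± 0.529. Tryptophan 6 had the lowest B cell (-2.02), plasma cell (2.84), Paneth (5.67) and thymus (0.623) means of its group. Antigen presentation genes were lower (median -0.40, 18 of 18 negative, adjusted p = 8.88e-09; adjusted p = 0.158 with an estimated correlation). The Ahr targets (adjusted p = 0.919) and the tryptophan metabolism list (adjusted p = 0.333) were not called.

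Naproxen plus tryptophan was compared with control in 7 and 8 jejuna. Retreg1 encodes a receptor for autophagy of the endoplasmic reticulum, Selenop a selenium carrier, and Fut2 a fucosyltransferase of the mucosal surface. edgeR called 0 genes (1028 at an unadjusted p below 0.05), DESeq2 10 and voom 3. Retreg1 had the lowest p (log2 -0.97, adjusted p = 0.139), at 89.4 ± 20.8 CPM in controls and 46.4 ± 20.1 CPM with the combination. Its difference was 0.13 in dissection batch 1 and -1.52 to -1.29 in batches 2 to 4. It was followed by Cemip (log2 1.17), Smox (log2 0.70), Fut2 (log2 1.55) and Selenop (log2 -0.90). Ribosomal protein genes were lower (median -0.28, 40 of 40 negative, adjusted p = 5.55e-14; adjusted p = 0.547 with an estimated correlation). Goblet cell genes were lower (median -0.35, 13 of 13 negative, adjusted p = 3.68e-06; adjusted p = 0.545 with an estimated correlation), with Zg16 at log2 -0.56. Naproxen plus tryptophan 7 had the lowest goblet and Paneth means of its group (6.86 and 4.29 log2 CPM), with 12.0% of counts from mitochondrial transcripts and 20.6% from Rn7s1. Erythroid markers were higher (7 of 7 positive, adjusted p = 0.000148; adjusted p = 0.51 with an estimated correlation), 6 of them called when adjusted over the list alone, and their mean was highest in naproxen plus tryptophan 2 (4.25 log2 CPM, group 2.12 ± 1.34). The tryptophan metabolism list was lower (15 of 17 negative, adjusted p = 0.0067; adjusted p = 0.51 with an estimated correlation).

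Against naproxen alone, the combination left edgeR with 0 called genes in 7 and 7 jejuna (629, or 3.66%, at an unadjusted p below 0.05), DESeq2 with 10 and voom with 0. Ccl7, which encodes a monocyte chemokine, and Cyp2e1 were among the genes with the lowest p (log2 2.08 and 2.21, adjusted p = 0.996 each). Cell cycle genes were higher (median 0.26, 33 of 33 positive, adjusted p = 8.16e-16; adjusted p = 0.464 with an estimated correlation). B-cell markers were lower (median -3.51, adjusted p = 3.12e-14; adjusted p = 0.361 with an estimated correlation), with 12 of 12 called when adjusted over the list alone. Such markers depend on whether a Peyer's patch, the lymphoid follicle of the gut wall, lies in the sampled piece. White adipocyte markers were higher (median 1.17, 12 of 12 positive, adjusted p = 0.000366; adjusted p = 0.464 with an estimated correlation).

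The interaction of naproxen and tryptophan in the jejunum asked whether their joint effect departs from the sum of the single effects on the log2 scale. Igtp and Irgm2 encode GTPases induced by interferon. edgeR called 0 genes (584, or 3.4%, at an unadjusted p below 0.05), DESeq2 2 and voom 0, with Ccl7 at the lowest p (log2 3.07, adjusted p = 0.772). Interferon-stimulated genes were positive as a list (median 0.47, 34 of 38, adjusted p = 4.41e-09; adjusted p = 0.266 with an estimated correlation), among them Irgm2 at log2 1.13. T and NK cell markers were positive (median 0.55, 16 of 18, adjusted p = 8.69e-07; adjusted p = 0.266 with an estimated correlation). B-cell markers were negative (median -3.78, 12 of 12, adjusted p = 1.01e-08; adjusted p = 0.266 with an estimated correlation).

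Comparisons were set side by side across all tested genes, which are not independent replicates. The naproxen log2 fold changes of females and males of experiment 1 correlated at r = 0.16 (rank correlation 0.00667, 46.9% of genes with the same sign), those of females of experiment 1 and experiment 2 at r = 0.277 (rank 0.203), and those of males and experiment 2 at r = -0.103 (rank -0.156). Naproxen and naproxen plus tryptophan shared their controls, and their fold changes correlated at r = 0.532 in experiment 2, where simulated data without any effect gave 0.443. With the controls split between the comparisons, that correlation was 0.176. In the jejunum the corresponding values were 0.549, 0.462 and 0.0771. Celecoxib and naproxen correlated at 0.236, against 0.47 in simulation and -0.162 with the controls split. For celecoxib and tryptophan these values were 0.57, 0.491 and -0.0612. Naproxen in the heart of experiment 2 and in the jejunum, whose library types differed, correlated at r = -0.0915, and tryptophan in experiment 3 and the combination in experiment 2 at 0.139.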

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

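All tests of the 3 patterns weighed in this part were chosen after the results they concern had been seen; the search for samples far from the others was planned. Of 329 groups of named genes and marker lists tested, 18 held a library whose gap to the nearest other, over the range of its group, passed Dixon's 95% limit. Chance flags about 1 in 20 groups, so a number of this size needs no cause. Genes were searched only in groups with a mean of at least 1 CPM, and that floor was set after a first search had been seen. In the hearts these were Sema6a (9.37 CPM, lowest) and Afdn (58 CPM, lowest) in control 8 of experiment 2, Adam22 in control 1 (24.3 CPM, highest), and Slc25a33 in control male 10 (22.2 CPM, highest). Ppfia1 was highest in naproxen male 10 (55.5 CPM) and lowest in naproxen 1 of experiment 2 (34.4 CPM), where Fnip2 was lowest too (17.6 CPM). Fam13c stood highest in naproxen 6 of experiment 2 (7.13 CPM) and Col14a1 in control male 8 (18.8 CPM). In the jejunum, control 1 was highest for Ptgs1 (150 CPM) and Smox (21.5 CPM), naproxen 7 was lowest for Plaat3 (13.4 CPM) and H2ac18 (13.1 CPM), and celecoxib 8 was highest for Card14 (23.2 CPM). Among the marker lists (mean log2 CPM), the erythroid mean was highest in control male 10 (5.85), the B-cell mean in naproxen 3 of experiment 2 (3.09) and in jejunum celecoxib 1 (2.74), and the white adipocyte mean was lowest in jejunum control 2 (0.866). Libraries with 2 such values were control male 10, control 8 and naproxen 1 of experiment 2, and jejunum control 1 and naproxen 7.

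A difference between groups singled out Per2, whose naproxen effect differed between experiment 2 and the females of experiment 1 (log2 -0.982, adjusted p = 0.000669 in edgeR, a test of the difference itself). Per2 averaged 23.7 CPM in the control females of experiment 1 and 48.3 CPM in the controls of experiment 2, a difference that was not tested. Per2 oscillates over the day, and neither collection time nor the role of injections was tested for it.

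The first pattern weighed is the rise of erythroid transcripts in naproxen hearts, by 2.09 in females of experiment 1 (exact permutation p = 0.0317), 0.724 in males (exact p = 0.349) and 0.659 in experiment 2 (exact p = 0.138), as mean log2 CPM scaled over the pooled hearts, where the report scales within each experiment. More blood left in the naproxen hearts would raise red cell precursor transcripts and globins alike. Precursor transcripts, among them Slc4a1, Alas2 and Bpgm, exceeded globins by 0.448 more in naproxen hearts (permutation p = 0.00677 within strata, from 100000 permutations), with 0.489 (exact p = 0.238), 0.221 (exact p = 0.413) and 0.573 (exact p = 0.018) in the 3 strata, of which only that of experiment 2 passes alone; the pooled value argues against residual blood of unchanged composition as the whole cause. The same value fits a larger share of immature red cells, which remains a hypothesis because it was found and tested on the same hearts. Reticulocytes were not counted, and an effect of naproxen on bleeding or red cell production may contribute but was not measured.

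The second pattern is the rise of neutrophil transcripts in naproxen hearts of experiment 2, by 1.91 in mean log2 CPM, with 7 of 7 naproxen hearts above the highest of 8 controls (exact permutation p = 0.000155, the smallest that 6435 splits can give). More blood in the hearts would raise globins too, but globins rose by 0.344 (exact p = 0.451), and the neutrophil mean rose by 1.57 more than the globin mean (exact p = 0.00917). A single naproxen heart is argued against as well: without the highest, naproxen 7, the difference was 1.8 (exact p = 0.000333). With tryptophan added, the neutrophil mean was lower than on naproxen alone (difference -1.41, exact p = 0.00404). Of the lists fixed beforehand, this one was picked for its result in these same naproxen and control hearts. The p-values of the neutrophil mean therefore partly restate that choice and are not independent support. A lower mean beside a group picked for being high can also arise without an effect of tryptophan. More neutrophils in the blood or in the tissue may explain the values and cannot be separated from each other here. The males of experiment 1 showed no such rise (-0.551 in controls, -0.804 with naproxen), while the females spread widely (1.06 ± 2.24 with naproxen). The controls of experiment 3, also PBS-injected females, stood at 0.247 ± 0.89 over 6 tested members, against -1.52 ± 0.344 over 8 in the controls of experiment 2. Whether the controls of experiment 2 were unusually low was not tested.

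The third pattern is the set of 14 genes called for naproxen in the pooled hearts, which may reflect a shift of the clock, blood in the hearts or an effect of naproxen in heart cells. With 2 components of the clock list as covariates, their log2 fold changes kept a median of 79.9% (64.4% to 102%) and 14 of 14 kept their sign, but 0 of 14 stayed called in edgeR (adjusted p = 0.0846 to 0.343); the median standard error went from 0.0892 to 0.0885, and the fold of Rhobtb1 shrank from 0.46 (standard error 0.09) to 0.30 (0.06), but that of Fam13c went from -0.27 (0.05) to -0.28 (0.06) and lost its call too (adjusted p = 0.0846), so smaller folds do not account for each lost call and their cause was not tested. With the erythroid score as covariate, the median kept was 90.9% (28.2% to 126%) and 3 of 14 stayed called, while the median standard error rose to 0.1, with Rhobtb1 at 0.42 (0.10). As first written, a median over 75% would have counted against each of these explanations; a second condition, that more than 7 of the 14 stay called, was added after the values were seen, so both are read the same way and stay open. Slopes on the clock list among the hearts of experiment 3 gave a median of 20.6% of the observed fold changes with 10 of 12 genes in the same direction (females of experiment 1 15.4% with 9 of 11, males 42.5% with 6 of 11 and a range of -124% to 98.7%, and females with slopes of experiment 2 28.6% with 9 of 12 and a range of -70.4% to 132%), in a test tried before its criterion was written, so a shift of the clock and an effect of naproxen outside it cannot be told apart, because collection times are not given.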

How the results depend on the processing

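Chosen only after the data were seen were the fits with 1, 2 or 3 surrogate variables, the clock components and erythroid score as covariates, DESeq2 without the filter and the omission of libraries that stood apart; the other alternatives were fixed before. Counts below are genes called, in edgeR unless another tool is named, with the count of the report first where the comparison is first named. Of 204 counts under settings other than omission of 1 library, 105 stayed within 1.5 times the reported count and 99 moved. RLE scaling moved none of them. Named genes kept their direction and their side of the threshold in 1119 of 1500 values, lost their call in 226, gained one in 146 and changed sign in 8; DESeq2 gave no adjusted p for Cryba4 in 1. Gene lists depended most on the correlation assumed: of 261 calls, 1 stayed with an estimated correlation, 10 with fry, 260 with RLE scaling and 243 without the filter.

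DESeq2 called more genes than edgeR in the hearts: pooled naproxen 48 (14 in edgeR), females 54 (2), males 32 (0), interaction with sex 1 (0), males against females 59 (23), naproxen in experiment 2 6 (0), naproxen plus tryptophan against control 477 (41) and against naproxen 80 (15), experiment 2 against experiment 1 9 (1), and tryptophan 2 (0). In the jejunum it called 94 for naproxen (2), 10 for naproxen plus tryptophan against control (0), 10 against naproxen (0), 2 for the interaction (0) and 291 for naproxen against celecoxib (0). These held all 14 genes of the pooled count and 38 of the 41. In simulated females of experiment 1, 17.6% of DESeq2 calls were false. Voom called 38 in the pooled hearts, 0 in females, 23 in males, 7 for naproxen in experiment 2, 2830 for the combination against control, 563 against naproxen and 5 for experiment 2 against experiment 1. In the jejunum it called 0 for naproxen and 3 for naproxen plus tryptophan. The cause of these differences was not tested.

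Without the filter on low counts, the pooled count was 8, males 1, the combination against control 9 and against naproxen 0, with 29372 genes in place of 16085 in the adjustment for experiment 2. In the other direction, tryptophan in experiment 3 reached 179, and the jejunum 319 for celecoxib, 1182 for naproxen, 253 for tryptophan, 476 for naproxen plus tryptophan, 333 for that against naproxen, 319 for the interaction and 1784 for naproxen against celecoxib. Most of these were genes that the filter keeps (1129 of the 1182), and the cause was not tested. DESeq2 without the filter called 19, 139, 15, 40, 34, 31 and 295 in the same 7 comparisons of the jejunum, of which 0, 92, 0, 16, 13, 6 and 289 were genes that the filter keeps.

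With 1 surrogate variable the pooled count was 23, females 0, the combination against control 122, jejunum naproxen 0 and jejunum naproxen plus tryptophan 3. With 2 it was 0 in females, 12 for the combination against control, 29 against naproxen, 74 for jejunum naproxen, 6 for jejunum naproxen plus tryptophan and 20 for naproxen against celecoxib. With 3 it was 0 in females, 49 for males against females, 9 for the combination against control, 46 against naproxen, 4 for tryptophan in experiment 3, 9 for jejunum naproxen, 38 for jejunum naproxen plus tryptophan and 308 for naproxen against celecoxib. The cause was not tested.

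With the clock components as covariates the pooled count was 0, females 0, naproxen in experiment 2 2, the combination against control 1 and against naproxen 0, and experiment 2 against experiment 1 0. With the erythroid score it was 4 in the pooled hearts, 0 in females, 31 in males and 8 for the combination against control. With females only (10 and 15 libraries) the pooled count was 0, and with experiment 1 only it was 14, of which 5 were genes of the pooled count. With only the compared groups in the model, females gave 4, males 1, males against females 15, naproxen in experiment 2 4, the combination against control 231 and against naproxen 0, jejunum celecoxib 1 and jejunum naproxen 0. Without dissection batch, jejunum naproxen gave 0. A smooth muscle score as covariate gave 10 for jejunum naproxen and 525 for naproxen against celecoxib. For these the cause was not tested.

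The libraries that stood apart were picked after their values were seen, in part on the erythroid values themselves: naproxen females 1 and 3 and naproxen male 9, naproxen plus tryptophan heart 4, and jejunum naproxen 1 and naproxen plus tryptophan 2 and 7. Without them the pooled count was 4, females 1, the interaction with sex 1, the combination against control 65 and against naproxen 42, experiment 2 against experiment 1 2, jejunum naproxen 1 and jejunum naproxen plus tryptophan 1. With the replicate number as a replicate block the pooled count was 6, males 6, the combination against control 4 and against naproxen 0, experiment 2 against experiment 1 7, jejunum naproxen 5 and naproxen against celecoxib 1. Libraries with the same number did not vary together (median correlation -0.0469, 0.0246, -0.196 and 0.00035 in experiments 1 to 4), so the numbers pair no samples. Why the block moved these counts was not tested, and other counts stayed within 1.5 times.

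Omission of 1 library moved 91 of 293 counts. The pooled count ranged from 6 to 42: 42 without naproxen 1 of experiment 2, 26 without control male 10, and 6 to 9 without controls 1, 2 and 5 or naproxen 2, 4 and 5 of experiment 2, control females 1 to 5, control males 6 to 9, naproxen females 3 and 5 or naproxen males 7, 9 and 10. Females ranged from 0 to 3, with 0 without control 1, 3 or 4 or naproxen 2, 3 or 5, and 1 without control 2 or 5. Males ranged from 0 to 3 (3 without control 8, 1 without naproxen 9), the interaction with sex from 0 to 1 (1 without control female 2) and males against females from 15 to 20 (15 without control female 2 or 4 or control male 8). Naproxen in experiment 2 ranged from 0 to 1 (1 without naproxen 6). The combination against control ranged from 7 to 83: 83 without naproxen plus tryptophan 8, 65 without 4, 7 to 10 without 1, 2, 3, 5, 6 or 7, and 7 to 13 without controls 1 to 6 or 8. Against naproxen it ranged from 0 to 42: 42 without naproxen plus tryptophan 4, 33 without naproxen 4, 7 and 6 without naproxen 5 and naproxen plus tryptophan 8, and 0 to 4 without naproxen 2, 3, 6 or 7 or naproxen plus tryptophan 1, 2, 3, 5, 6 or 7. Experiment 2 against experiment 1 ranged from 1 to 5 (5 without naproxen 4 of experiment 2, 2 without its controls 5 or 8, control female 2 or naproxen female 4).

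In the jejunum, naproxen ranged from 0 to 8: 8 without control 1, and 0 without controls 2 to 6 or naproxen 1, 2, 3, 4, 5 or 7. Naproxen against celecoxib ranged from 0 to 498: 498 without naproxen 6, 7 without naproxen 2, 6 without celecoxib 7 and 1 without naproxen 3. Tryptophan ranged from 0 to 1 (1 without tryptophan 4), naproxen plus tryptophan from 0 to 1 (1 without control 7 or naproxen plus tryptophan 7) and that combination against naproxen from 0 to 1 (1 without naproxen plus tryptophan 6). Celecoxib, the interaction and tryptophan in experiment 3 stayed at 0 in edgeR, with 751, 584 and 459 genes at an unadjusted p below 0.05 and 0, 2 and 2 calls in DESeq2.

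The sign changed only for Ptgs1 and Ptgs2 among named genes, which were not called in edgeR as reported; Ptgs1 was called under 1 alternative, jejunum naproxen without the filter (log2 0.41, adjusted p = 0.0434, range over the alternatives 0.0434 to 0.938). Ptgs2 turned to 0.058 in the pooled hearts with voom, to 0.063 for naproxen plus tryptophan in the heart with 3 surrogate variables, to -0.057 for jejunum naproxen with 1, and to 0.001 for celecoxib with 3. Ptgs1 turned to 0.017 for naproxen plus tryptophan in the heart with the clock components and to -0.024 for jejunum naproxen with 2 surrogate variables. For celecoxib Ptgs2 also turned to 0.031 with the replicate block and to 0.012 without dissection batch. With 1 library left out Ptgs2 ranged from -0.288 to 0.102 for celecoxib (highest without control 4), from -0.125 to 0.017 for tryptophan in experiment 3 (highest without tryptophan 2) and from -0.06 to 0.49 for jejunum naproxen plus tryptophan (lowest without that group's 2). Each value that turned lies within its standard error of 0. What depth limits was not separated from the spread between animals and from group size: in simulation, 36 of 67 genes changed 1.5-fold were recovered for jejunum naproxen and 54 of 67 for naproxen plus tryptophan in the heart.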

Other observations

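Both drugs act on prostanoid synthesis, and serum amyloid A marks acute responses of the gut epithelium. The prostanoid list (synthesis enzymes, receptors and transporters) was lower with celecoxib in the jejunum (18 of 22 negative, camera adjusted p = 0.0412; adjusted p = 0.582 with an estimated correlation) and was not called with naproxen there (adjusted p = 0.788) or in the pooled hearts (adjusted p = 0.514). Saa1 was among the lowest p of its list with celecoxib (log2 4.26) and with naproxen plus tryptophan (log2 5.30), and Duoxa2, a maturation factor of the dual oxidase of the epithelium, had log2 2.28 with the combination. None of these genes was called over all genes by edgeR. They were chosen after their values were seen.

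Interferon-stimulated genes were lower in the naproxen jejunum (median -0.30, 32 of 38 negative, adjusted p = 1.72e-05; adjusted p = 0.521 with an estimated correlation), among them Ido1, and so were antigen presentation genes (median -0.26, 15 of 18 negative, adjusted p = 0.000582; adjusted p = 0.521 with an estimated correlation), with Psmb8 of the immunoproteasome at log2 -0.93 (adjusted p over all genes = 0.0898). Genes of lipid absorption were lower there as well (median -0.31, 18 of 20 negative, adjusted p = 7.59e-05; adjusted p = 0.521 with an estimated correlation), with the fatty acid carrier Cd36 at log2 -0.90 and the colipase gene Clps at -1.25. Clps is a pancreatic transcript, and the exocrine pancreas list was lower as well (1.45 ± 0.376 in controls and 0.945 ± 0.6 with naproxen, mean log2 CPM; 4 of 5 tested members negative, adjusted p = 0.0233; adjusted p = 0.521 with an estimated correlation; fry adjusted p = 0.0447). In the heart of experiment 2, edgeR called Cp, which encodes ceruloplasmin (log2 -0.44, adjusted p = 0.0454), Galnt15 (log2 -0.40, adjusted p = 0.0454) and Rgs3, a regulator of G-protein signalling (log2 -0.30, adjusted p = 0.0454) lower with the combination; with 1 library left out these calls held in 3, 4 and 2 of 16 omissions.

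All libraries of the labels belong to a compared group, so no library stands outside the comparisons. For each of the 17 comparisons, 100 splits of its libraries into groups of the same sizes, the real one included, were fitted with edgeR. Splits were drawn within strata or dissection batches where these were in the model. The tests were planned, but a first run drew fewer splits and counted mirror images separately. The larger number with mirrors merged changed some of the outcomes. Few splits matched the pooled naproxen count of called genes (14, as many in 2 of 100 splits, 16 in the highest other). The same held for males against females among controls (23, as many in 2 splits, 1756 in the highest other). It held too for naproxen plus tryptophan in the heart against control (41, as many in 4 splits, 653 in the highest other). The last such comparisons were that combination against naproxen (15, as many in 3 splits, 880 in the highest other) and naproxen in the jejunum (2, as many in 2 splits, 237 in the highest other). For these 5, as many genes at an unadjusted p below 0.05 were found in 21, 17, 6, 12 and 10 of 100 splits, in the same order. Each comparison was judged alone, with no allowance for the 17 comparisons. By themselves the splits therefore do not exclude chance for any of these 5. Males and females nevertheless differ, as Xist (adjusted p = 3.05e-13 in edgeR) and the Y-linked genes show. The number of matching splits thus does not set this known difference apart from the other comparisons. Chance could not be excluded for naproxen in females of experiment 1 (2 genes, as many in 5 splits, 135 in the highest other) or for the effect of experiment 2 against experiment 1 (1 gene, as many in 9 splits, 2708 in the highest other).

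In the 10 comparisons with 0 called genes in edgeR, 100 of 100 splits gave as many, so the count says nothing against chance; the unadjusted counts and those of DESeq2 and voom stand in the report. The highest other splits called 4 genes for naproxen in males and 0 for the interaction with sex, 1588 for naproxen in experiment 2 and 1712 for tryptophan in experiment 3. In the jejunum they called 0 for celecoxib, 0 for tryptophan, 1 for naproxen plus tryptophan, 7 for that combination against naproxen, 27 for the interaction and 3250 for naproxen against celecoxib. Splits that call several times the real count, as in experiments 2 and 3 and in the jejunum for naproxen and for naproxen against celecoxib, point to a structure of the samples other than the labelled groups, which was not tested further.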
